A study of Homo sapiens with 32 samples.

How the data were processed

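RNA-seq gene counts were analysed from 32 libraries of 2 human breast cell lines: 15 libraries of MCF12A, a non-tumorigenic mammary epithelial line, and 17 of MCF7, an estrogen receptor-positive breast cancer line. Each line had 5 groups: untreated cells, cells given 1 mM octyl-2HG (an octyl ester of 2-hydroxyglutarate, a form that crosses membranes), cells given 1 mM of a control compound that the labels do not name, cells transfected with an empty vector, and cells transfected to overexpress ADHFE1. Groups held 3 libraries, except 4 for octyl-2HG and 4 for untreated cells in MCF7. The design text of the series names the non-tumorigenic line MCF10A, whereas the label of every such library reads MCF12A, and the name on the libraries is used here. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

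Per the labels' protocols, RNA was isolated with Trizol and libraries were built with an Illumina kit from total RNA. Per the submitters' processing notes, TopHat and HTSeq were used with the human genome build hg19; their versions and settings, and whether counting used strand, were not given in the sources used here. The deposited values are raw counts per Ensembl gene ID, with no normalization by the authors. The table held 56299 gene IDs, of which 15728 had 0 counts in all 32 libraries, and each of its 32 columns was matched to a library by the name in the label. Because the way reads were shared among paralogs and overlapping genes was not stated, values of genes with near-identical copies (such as KRT81, HSPA1A, HSPA1B and UGT2B15), of pseudogenes and of antisense or unnamed loci are uncertain. Coordinates are not given, because no annotation of hg19 was used here.

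Symbols were attached from a table of current gene names, which held 46802 of the 56299 IDs; the other 9497 keep their ID. Transcript length and GC content came from GENCODE release 29, as properties of genes only. Before the data were examined, 32 gene lists with 732 members were fixed, covering breast lineage and differentiation, metabolism (including 2-hydroxyglutarate and the dioxygenases that use 2-oxoglutarate), stress and signalling programmes, proliferation and markers of other cell types. Of these members, 722 matched a gene ID. All 32 libraries had 0 counts on mitochondrially encoded genes, so 31 lists were tested.

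Counts per library summed to between 3.253 M and 31.387 M (median 16.294 M). The ranges in M counts were, in MCF12A, 15.369 to 22.7 for octyl-2HG, 16.045 to 25.698 for the control compound, 3.253 to 31.387 for untreated cells, 9.152 to 26.554 for empty vector and 9.255 to 24.252 for ADHFE1. In MCF7 they were 15.329 to 17.581 for octyl-2HG, 10.125 to 15.558 for the control compound, 12.254 to 17.233 for untreated cells, 15.105 to 18.818 for empty vector and 14.884 to 22.597 for ADHFE1. Where a library had no count of a gene, 3 counts was taken as the limit that a count of 0 allows, which is 0.0956 CPM (counts scaled to library size) in the deepest library and 0.9222 CPM in the shallowest. A fold against a group at 0 is a lower bound computed against 3 counts over that whole group. These limits cover counting error only, as reads carried no molecular identifiers.

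Libraries were scaled with TMM factors, and genes were tested with the quasi-likelihood test of edgeR 4.0.16 (limma 3.58.1, R 4.3.3) with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. All libraries of a line entered 1 fit per line, so that its groups shared the estimate of spread, on genes kept by edgeR's default expression filter (15267 in MCF12A and 15547 in MCF7). The difference of an effect between lines was tested as an interaction in a fit of all 32 libraries (17242 genes), coded as MCF7 minus MCF12A. CPM values are TMM-scaled and given as mean ± SD, and log2 fold changes are given ± SE. The standard error was computed as the size of the log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 12.2% in MCF12A and 21.6% in MCF7.

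Lists were tested with limma's camera, which asks whether a list's genes moved more than the other genes, at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each list was tested again with a correlation estimated from its own genes, and with fry. The named genes of a comparison were set by a rule fixed before the data were examined: the 10 genes with the largest log2 fold change in each direction (5 in comparisons with untreated cells and in interactions) among those past the threshold, with an average log2 CPM of at least 2 and with no overlap between the libraries of the groups, plus ADHFE1 and members of the fixed lists. Genes named outside that rule are said to have been chosen after their values were seen.

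The test was run first on simulated counts with known changes, drawn from the means and depths of the real libraries. For ADHFE1 in MCF12A (14771 genes) it recovered 62.1% of 1.5-fold, 78.1% of 2-fold and 81.5% of 4-fold changes. For ADHFE1 in MCF7 (15136 genes) it recovered 6.25%, 42.4% and 81.5%, for octyl-2HG against the control compound in MCF12A (14761 genes) 49.2%, 71.9% and 100%, and for the same comparison in MCF7 (15161 genes) 4.84%, 47.6% and 79.7%. In the simulated interaction (16667 genes) 71.7% of 4-fold changes were recovered. Each simulation made between 3 and 12 false calls.

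No 2 libraries agreed within sampling noise (the lowest chi-square per degree of freedom of any pair in a group was 1.797). Replicate numbers in the labels were checked for pairing through the correlation of same-numbered libraries' deviations from their group means. Every pair was above 0.1 only for octyl-2HG against untreated MCF7 cells (0.11 to 0.23, 4 pairs) and for the control compound against untreated MCF7 cells (0.5 to 0.67, 3 pairs). Even there, not every library correlated best with the library of its own number, so pairing is possible but not established. With the replicate number as a block these 2 comparisons gave 9208 and 9774 called genes in place of 7786 and 8788.

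Alternatives fixed before the data were examined were DESeq2 1.42.0, its size factors within edgeR, no expression filter, a stricter filter (average log2 CPM of at least 1), fits of only the groups compared, the replicate number as a block, the other list tests and leaving out each library in turn. After the data were seen, 4 were added: testing the list of 2HG and glutamine metabolism without ADHFE1, removing each library's trend with transcript length and GC content, leaving out gene IDs without a symbol, and leaving out 5 libraries that stood apart. Of these 5, MCF7 control compound 2, untreated 1, untreated 2 and empty vector 2 had log2 CPM that fell by more than 0.1 per doubling of transcript length relative to the mean library of the line, and MCF12A untreated 2 had over 20% of its counts on IDs without a symbol. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.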

Results

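The data collected were counts of RNA-seq reads per gene in 32 libraries from 2 human breast lines, 15 from the non-tumorigenic epithelial line MCF12A and 17 from the estrogen receptor-positive cancer line MCF7. Both lines had 5 groups: untreated cells, 1 mM octyl-2HG, 1 mM of an unnamed control compound, empty vector and ADHFE1 overexpression. Groups had n = 3 libraries, apart from MCF7 octyl-2HG and untreated MCF7 cells with n = 4. Total counts ran from 9.152 M to 31.387 M in 31 of the libraries and came to 3.253 M in MCF12A untreated 2. Values below are CPM (counts scaled to library size, mean ± SD over libraries) and log2 fold changes (± SE) from edgeR, with adjusted p over all genes tested.

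ADHFE1 (ENSG00000147576) encodes hydroxyacid-oxoacid transhydrogenase, a mitochondrial enzyme that oxidises 4-hydroxybutyrate while reducing 2-oxoglutarate to D-2-hydroxyglutarate (2HG). In tumors with mutant isocitrate dehydrogenase, 2HG accumulates and inhibits enzymes that need 2-oxoglutarate, among them DNA and histone demethylases. The design raises the enzyme in 1 arm and supplies a membrane-crossing ester of its product in the other, so it asks which genes respond to each in a normal-like and a cancer line. Levels of 2HG itself were not analysed here.

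ADHFE1 transcript was low without overexpression. Untreated MCF12A cells had 1.23 ± 0.333 CPM and untreated MCF7 cells 2.26 ± 0.301 CPM, and with empty vector the levels were 2.81 ± 0.298 and 1.56 ± 0.216 CPM. Overexpression brought ADHFE1 to 73.9 ± 6.06 CPM in MCF12A (log2 fold change 4.68 ± 0.15 against vector, adjusted p = 9.59e-17) and to 792 ± 82.6 CPM in MCF7 (8.99 ± 0.22, adjusted p = 9.67e-13). In MCF12A, the octyl-2HG group had less endogenous ADHFE1 (0.118 ± 0.0458 CPM) than the control compound group (0.732 ± 0.286 CPM), with a log2 fold change of -2.51 ± 0.41 (adjusted p = 4.98e-05). In MCF7 the corresponding groups had 2.09 ± 0.36 and 1.52 ± 0.389 CPM, a difference of 0.45 ± 0.20 that did not pass (adjusted p = 0.119).

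**Figure D1:**
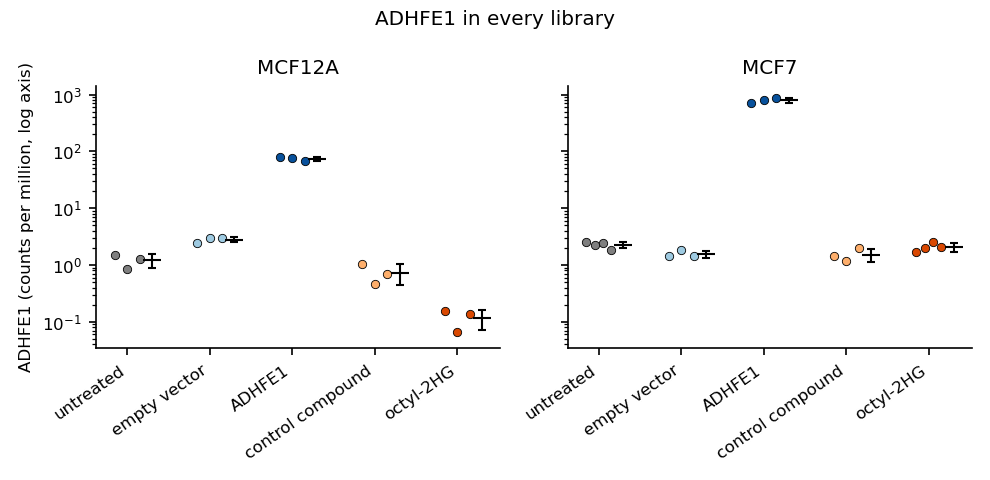
ADHFE1 in each of the 32 libraries, in CPM on a log axis, by group and line; points are libraries and bars the mean ± SD. Libraries with ADHFE1 overexpression lay between 67.4 and 79.3 CPM in MCF12A and between 707 and 871 CPM in MCF7, above every other library of their line.

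The comparisons differed widely in how many genes passed the threshold. ADHFE1 against empty vector called 9691 of 15267 genes in MCF12A (4778 up and 4913 down) and 47 of 15547 in MCF7 (6 up and 41 down). Octyl-2HG against the control compound called 6475 genes in MCF12A (3108 up, 3367 down) and 4095 in MCF7 (2216 up, 1879 down). At 2-fold or more the counts were 1821 up and 1752 down, 2 up and 36 down, 622 up and 641 down, and 1032 up and 458 down, in the same order. The 47 genes of MCF7 depended on the setting: they became 2 when only their groups were fitted, 174 with DESeq2, 112 with the replicate number as a block, 109 with trends in transcript length and GC content removed, and 277 without the 5 libraries whose composition stood apart (empty vector 2 in this comparison). They became 25, 18 and 19 without ADHFE1 1, 2 and 4, and 24 without empty vector 1. Without empty vector 2 alone they became 33, so leaving out that library by itself did not raise the count. The 4095 genes of octyl-2HG in MCF7 became 6939 without the libraries that stood apart (3399 up, 3540 down), and fewer rose than fell also with DESeq2 (2200 and 2429) and with its size factors in edgeR (2019 and 2106).

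**Figure D2:**
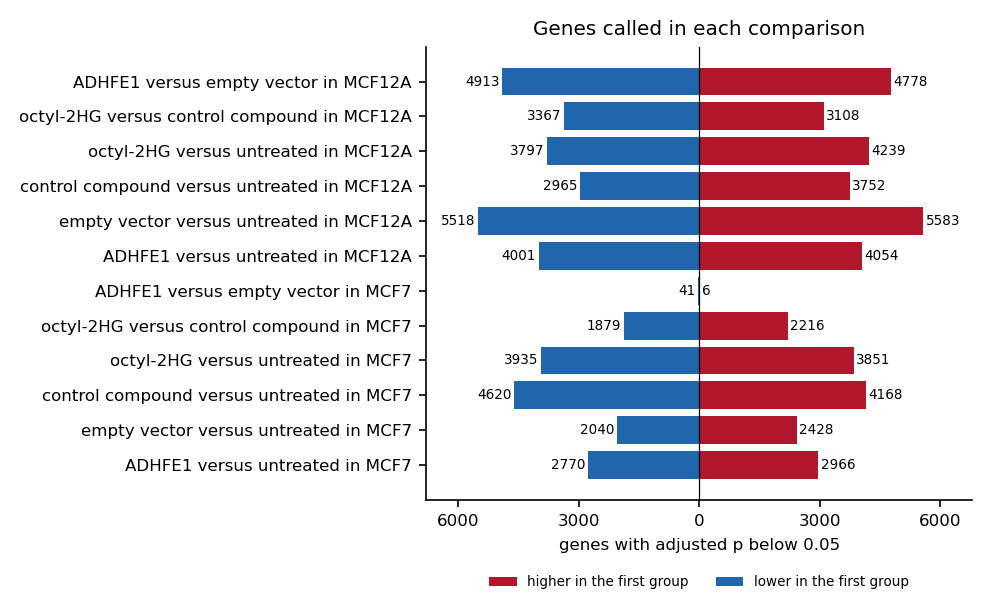
Bars give the number of genes past an adjusted p of 0.05 in each of 12 comparisons, higher (right) and lower (left) in the group named first. Empty vector against untreated cells in MCF12A had the most (5583 up and 5518 down), and ADHFE1 against empty vector in MCF7 the fewest (6 up and 41 down).

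The first comparison sets raised ADHFE1 against empty vector in a non-tumorigenic mammary epithelial line. Such cells have a mixed basal and luminal character, carrying basal keratins and the basal transcription factor TP63 beside luminal keratins. Increases and decreases here are relative to empty vector, whose libraries were themselves far from untreated cells. Only 2604 of the 9691 called genes were also called in the same direction between ADHFE1 and untreated cells. The genes with the largest increase over empty vector were these. PKP1, a desmosomal plaque protein of stratified epithelium, rose from 11.9 ± 0.537 to 710 ± 6.88 CPM (5.90 ± 0.12, adjusted p = 1.24e-19). ATF3, a stress-induced transcription factor, rose from 3.7 ± 0.296 to 362 ± 6.78 CPM (6.63 ± 0.28, adjusted p = 2.1e-10). GLDC, the glycine decarboxylase of the mitochondrial glycine cleavage system, rose from 0.167 ± 0.0995 to 23.6 ± 3.1 CPM (6.95 ± 0.24, adjusted p = 2.92e-16). The cell cycle regulator CCND2 rose from 0.156 ± 0.0427 to 22.5 ± 1.38 CPM (7.0 ± 0.56, adjusted p = 3.59e-07). AUTS2, a chromatin-associated neurodevelopmental gene, had no count with empty vector and 5.93 CPM with ADHFE1, at least 128-fold higher. PTPRZ1 (log2 fold change 7.04, from 4 counts with empty vector), HAP1 (5.92), the receptor kinase FGFR3 (5.89) and SYT14 (5.67) completed this group, as did the monocarboxylate transporter SLC16A9, which had 1 count in the empty vector libraries. Untreated cells had 4.4 ± 0.502 CPM of AUTS2 and 25.2 ± 18.7 CPM of CCND2, near the ADHFE1 levels and far from the vector levels. Untreated levels of the other genes of this group are not given here.

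Genes with the largest decrease were highly expressed with empty vector and close to absent with ADHFE1. The interleukin-33 receptor IL1RL1 fell from 478 ± 23.4 to 0.492 ± 0.506 CPM (-10.1 ± 0.35, adjusted p = 1.08e-08). KRT81, a hair keratin whose reads may be shared with its close paralogs, fell from 702 ± 23.4 to 1.82 ± 2.08 CPM (-8.73 ± 0.44, adjusted p = 1.14e-08). The myosin-binding protein MYBPC1 fell from 162 to 0.447 CPM (-8.63 ± 0.16, adjusted p = 2.84e-16) and the lysosomal protease CTSF from 126 to 0.548 CPM (-7.88 ± 0.18, adjusted p = 6.22e-19). HS6ST2, a heparan sulfate sulfotransferase, had 18.3 ± 1.13 CPM with empty vector and no count with ADHFE1, at least 290-fold lower. SLC44A5 (-8.83) and PHACTR3 (-7.84) fell likewise, and IYD, ZNF83 and TMEM30B had 1, 3 and 3 counts with ADHFE1 against 20.6, 40.3 and 22.6 CPM with empty vector. In untreated cells IL1RL1, MYBPC1, IYD, TMEM30B and HS6ST2 had 0 CPM and ZNF83 0.0192 CPM, so the ADHFE1 libraries lay near the untreated level. KRT81 stood at 22.4 CPM in untreated cells, between the compared groups. Untreated levels of CTSF, SLC44A5 and PHACTR3 are not given here.

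Lineage genes moved in both directions in this comparison. Among 19 basal markers, 11 rose, 7 fell and 1 did not pass: KRT14 rose from 81 to 1220 CPM (3.91) and TP63 from 51.5 to 291 CPM (2.49), while KRT17 fell from 1440 to 81.8 CPM (-4.14). Among 16 luminal markers, 5 rose, 7 fell and 4 did not pass, with a median log2 fold change of 0.14 and a mean of -0.14, and NAT1 fell from 92.1 to 3.74 CPM (-4.61). Of 28 mesenchymal markers 10 rose, such as VIM (2.25, from 190 to 903 CPM), and 13 fell, such as FN1 (-5.15). Untreated cells had 50.7 CPM of KRT17 and 995 CPM of VIM, near the ADHFE1 level and far from the vector level. Their 149 CPM of TP63 lay between the levels of the compared groups. None of the basal, luminal and mesenchymal lists passed as a whole (adjusted p = 0.206 each). The markers of mammary stem and progenitor cells did pass, with 7 of 9 up and none down (adjusted p = 0.00051, and 0.0498 with an estimated correlation): SOX9 rose from 6.64 to 48.4 CPM, the receptor NOTCH1 from 180 to 1000 CPM, and CD44 from 270 to 513 CPM. Of 29 epithelial junction genes 18 fell, including CDH1 (E-cadherin, from 256 to 82.8 CPM) and RAB25 (from 118 to 1.3 CPM), 9 rose, among them MARVELD2, and 2 did not pass. That list was called down (adjusted p = 0.00264), but not with an estimated correlation (adjusted p = 0.651).

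The other called lists of this comparison lost their call with an estimated correlation. MYC targets of ribosome biogenesis had 28 of 33 genes up, 2 down and 3 not passing (adjusted p = 0.000181 and 0.558), for instance the nucleolar proteins NOLC1 (1.57) and RRS1 (1.19) and the purine enzyme GART (1.09). Chaperones of the endoplasmic reticulum had 16 of 20 genes down, 1 up and 3 not passing (adjusted p = 0.00397 and 0.693), for instance PDIA3 (-0.92), CALR (-0.94) and the secretory regulator XBP1 (-1.99). Fibroblast markers had 4 of 5 down and 1 not passing (adjusted p = 0.0166 and 0.649), with DCN from 410 to 69.8 CPM. The chemokine CXCL1 rose from 0.987 to 24.9 CPM within an NF-kB list that did not pass (9 up, 5 down, 5 not passing, adjusted p = 0.0682, but 0.0245 and 0.033 without ADHFE1 2 and 3). Estrogen-responsive genes split 10 up, 9 down and 2 not passing (adjusted p = 0.676; median 0.26, mean -0.01). For the 5 called lists, adjustment over the list alone gave the same counts.

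The empty vector libraries of MCF12A were farther from untreated cells than the ADHFE1 libraries were. Empty vector against untreated cells called 11101 genes, and ADHFE1 against untreated cells 8055. Of the 9691 genes called between ADHFE1 and empty vector, 7360 (75.9%) had their empty vector mean farther from the untreated mean than their ADHFE1 mean, and only 2604 were also called in the same direction between ADHFE1 and untreated cells. Among genes chosen after their values were seen, the methionine salvage enzyme MTAP had 6.04 CPM with empty vector and between 72.4 and 177 CPM in the other four MCF12A groups. IL1RL1 had 478 CPM with empty vector and 0 in untreated cells, KRT17 had 1440 and 50.7 CPM, and CCND2 had 0.156 and 25.2 CPM. Fold changes of ADHFE1 against vector in this line thus carry the distance of the vector libraries from untreated cells as well.

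In MCF7 the same overexpression tests the enzyme in a luminal cancer line that depends on estrogen receptor signalling. The 6 genes that rose were ADHFE1, SLC7A11, SCNN1A, DDIT4, CTSC and SCIN, the last chosen after its value was seen (1.32). SLC7A11, the cystine importer that supplies glutathione synthesis, rose from 11.6 ± 1.98 to 22.7 ± 2.79 CPM (0.96 ± 0.19, adjusted p = 0.0442). DDIT4, an inhibitor of mTORC1 induced by amino acid and energy stress, rose from 98.8 ± 3.5 to 157 ± 1.71 CPM (0.67 ± 0.13, adjusted p = 0.0436). The epithelial sodium channel subunit SCNN1A rose from 63.3 to 103 CPM (0.70 ± 0.12, adjusted p = 0.0181) and the protease CTSC from 38.4 to 56.3 CPM (0.55 ± 0.10, adjusted p = 0.0324). Leaving out any 1 of the 6 libraries ended the calls of SLC7A11, DDIT4 and CTSC, and leaving out any of 5 ended that of SCNN1A. With each library's trend in transcript length and GC content removed, SLC7A11 and CTSC did not pass.

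Most of the genes called in MCF7, 41 of 47, fell. ASCL1, a neuroendocrine transcription factor, fell from 7.82 ± 0.0503 to 0.94 ± 0.104 CPM (-3.06 ± 0.17, adjusted p = 1.07e-07), and the chemokine CXCL14 from 16.7 ± 6.21 to 1.4 ± 0.57 CPM (-3.57 ± 0.51, adjusted p = 0.00542). GPER1, a membrane receptor for estrogen, fell from 26.7 ± 0.843 to 8.45 ± 1.7 CPM (-1.65 ± 0.19, adjusted p = 0.00108). The survival gene BCL2 fell from 7.11 to 2.28 CPM (-1.63 ± 0.28, adjusted p = 0.0151), the zinc transporter SLC39A6 from 940 to 355 CPM (-1.40 ± 0.18, adjusted p = 0.00171) and the RAS-like growth inhibitor RERG from 23.2 to 11.4 CPM (-1.03 ± 0.14, adjusted p = 0.00217). The list of estrogen-responsive genes did not pass (2 down and 26 not passing, adjusted p = 0.0634, and 0.303 with an estimated correlation), and with 1 library left out its adjusted p ran from 8.76e-05 (without empty vector 2) to 0.379 (without empty vector 4), passing also without ADHFE1 2 (0.0301). The peptidase MME (-2.55), RGS22 (-2.40), the phosphatase DUSP13 (-1.94), TDRD1 (-1.88), the potassium channel KCNMA1 (-1.84) and RASGEF1B (-1.58) fell too, as did the growth factors TGFB1 (-1.13) and BMP7 (-1.14), chosen after their values were seen.

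Of the gene lists, 5 were called for ADHFE1 in MCF7. The list of 2HG and glutamine metabolism, the only one also called with an estimated correlation, had 1 gene up, ADHFE1 itself, and 17 not passing (adjusted p = 1.65e-06 and 0.0023), or 2 up when adjusted over the list alone; IDH1 was the other (252 against 179 CPM). Without ADHFE1, in a test added after the data were seen, that list did not pass (adjusted p = 0.749 and 0.946), so its call rested on the overexpressed gene. Genes of the ATF4 response to amino acid shortage had 2 up, DDIT4 and SLC7A11, and 28 not passing (adjusted p = 0.00149, or 0.873 with an estimated correlation, and 0.0533 without empty vector 4; 3 up when adjusted over the list alone). Luminal markers had 1 down, BCL2, and 19 not passing (adjusted p = 0.0226 and 0.125, and 0.0509 without empty vector 1; 3 down when adjusted over the list alone). Interferon-stimulated genes had none of 23 passing (adjusted p = 0.000597 and 0.128; 1 up and 9 down when adjusted over the list alone). Nuclear genes of oxidative phosphorylation had none of 33 passing under either adjustment, with a median of -0.51 (adjusted p = 6.81e-05 and 0.946). That call was lost without empty vector 2 alone (adjusted p = 0.0703). It was kept without all the libraries that stood apart, empty vector 2 among them, and with length and GC trends removed. The dioxygenases that use 2-oxoglutarate, which include the TET and KDM demethylases, had none of 24 passing (median 0.33, adjusted p = 0.0505 and 0.946). Leaving out 1 library took that p from 0.0174 (without empty vector 4) to 0.6 (without empty vector 2), and it passed also without ADHFE1 2 (0.0301) or empty vector 1 (0.0294). In simulated data this comparison recovered 42.4% of 2-fold changes, against 78.1% for ADHFE1 in MCF12A, and 1570 genes had an unadjusted p under 0.05.

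Octyl-2HG against the control compound in MCF12A sets equal 1 mM doses side by side, so it asks what the ester does beyond an unnamed compound of the same concentration. The vasoconstrictor peptide EDN2, a hypoxia-induced endothelin, rose from 0.145 ± 0.0244 to 19.1 ± 4.9 CPM (6.97 ± 0.31, adjusted p = 8.1e-12), whereas in MCF7 it did not differ between the compounds (0.04 ± 0.32). TSC22D3, the glucocorticoid-induced leucine zipper, rose from 80.5 ± 4.75 to 767 ± 222 CPM (3.25 ± 0.16, adjusted p = 3.88e-11). The sodium channel subunit SCNN1G, another steroid-regulated gene, rose from 5.25 ± 1.6 to 50 ± 7.15 CPM (3.29 ± 0.16, adjusted p = 5.55e-11). The matrix proteoglycan DCN rose from 1.04 ± 0.454 to 9.07 ± 1.39 CPM (3.2 ± 0.20, adjusted p = 4.77e-10) and the chemokine receptor CXCR4 from 1.9 to 13.6 CPM (2.95 ± 0.43, adjusted p = 0.000261). CNR1 (3.49), SORL1 (3.14), CCN5 (3.06) and the pseudogene IMPDH1P5 (2.74) rose as well. MMP7, with no count under the control compound, was at least 3.43-fold higher at 0.167 CPM (9 counts). Untreated cells had 3.25 CPM of MMP7, more than with either compound.

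Decreases in the same comparison included genes of cellular stress. CHAC1, a glutathione-degrading target of ATF4, fell from 30.2 ± 9.77 to 3.97 ± 1.42 CPM (-2.95 ± 0.22, adjusted p = 9.34e-09). The calcium-binding protein S100P fell from 143 to 23.6 CPM (-2.60 ± 0.20, adjusted p = 4.3e-07), the heat shock gene HSPA1A from 110 to 24.9 CPM (-2.16 ± 0.17, adjusted p = 9.24e-08) and the stress-induced NIBAN1 from 14.4 to 2.83 CPM (-2.39). HSPA1A and its copy HSPA1B are nearly identical, so reads cannot be assigned to either with certainty. MAP2 (-2.80), APPAT (-2.65), CFAP44 (-2.27) and LYPD3 (-2.22) fell too. IL1RL1 went from 0.375 ± 0.308 CPM (26 counts) to no count, at least 7.1-fold lower (adjusted p = 0.0246). It met the rule on average expression only through the empty vector libraries, which had 478 CPM.

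As groups, 13 of 31 lists were called in MCF12A, 10 up and 3 down, and none held with an estimated correlation. Hypoxia response genes had 18 of 30 up, 2 down and 10 not passing (adjusted p = 2.35e-10, or 0.0911 with an estimated correlation). Among them the carbonic anhydrase CA9 rose from 1.05 to 10.2 CPM, the peptide ADM by 2.19, the glucose transporter SLC2A1 from 128 to 287 CPM and the collagen hydroxylase P4HA1 from 87.2 to 177 CPM. Cholesterol synthesis genes had 19 of 25 up, none down and 6 not passing (adjusted p = 1.06e-11 and 0.171), with INSIG1 from 56.3 to 264 CPM, HMGCR from 110 to 253 CPM and the receptor LDLR from 212 to 430 CPM. NRF2 antioxidant genes had 20 of 25 down, 1 up and 4 not passing (21 down when adjusted over the list alone; adjusted p = 3.36e-12 and 0.139). The reductase AKR1C2 fell from 162 to 44.2 CPM, NQO1 from 611 to 272 CPM and SLC7A11 from 138 to 55.8 CPM. Mesenchymal markers had 17 of 28 up, 2 down and 9 not passing (adjusted p = 2.77e-08 and 0.0533), among them SERPINE1 (from 422 to 1760 CPM), ITGA5 (from 275 to 831 CPM) and LOX (1.58).

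The other nine called lists of MCF12A were these. NF-kB genes had 10 up, 3 down and 6 not passing (11 up when adjusted over the list alone; adjusted p = 0.000818 and 0.171), with BIRC3 (2.23), TNFAIP3 (1.40) and NFKBIA (1.06). Targets of p53 had 13 up, 4 down and 7 not passing (adjusted p = 0.00114 and 0.469), with DDB2 (1.18), CCNG1 (1.08) and MDM2 (0.67). Fibroblast markers had 3 of 5 up, with a median of 1.05 (adjusted p = 0.00114 and 0.171). Glycolysis had 8 up, 1 down and 11 not passing (adjusted p = 0.00332 and 0.647), the tricarboxylic acid cycle 13 up, 2 down and 8 not passing (adjusted p = 0.00358 and 0.592) and oxidative phosphorylation 14 up and 19 not passing (adjusted p = 0.00693 and 0.666). IDH2, the mitochondrial isocitrate dehydrogenase, rose from 32.3 to 65 CPM. Estrogen-responsive genes had 7 up, 2 down and 12 not passing (adjusted p = 0.0228 and 0.238). Genes of the ATF4 response had 14 down, 4 up and 13 not passing (adjusted p = 0.00332 and 0.666). Neither of these lists passed without control compound 4 (adjusted p = 0.0582 each). Heat shock genes had 7 down, 5 up and 3 not passing (adjusted p = 0.0281 and 0.465), with a median of 0.00 and a mean of -0.30, and did not pass with the replicate number as a block (0.0614) or with length and GC trends removed (0.0577).

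In MCF7, whose growth depends on the estrogen receptor, the same pair of compounds was compared with 4 octyl-2HG libraries against 3. MME, a cell-surface peptidase, rose from 7.97 ± 1.97 to 84.5 ± 6.21 CPM (3.39 ± 0.22, adjusted p = 1.51e-07) and NT5E (CD73), which makes adenosine, from 7.3 ± 0.42 to 75.3 ± 13 CPM (3.37 ± 0.18, adjusted p = 4.33e-08). RGS22 rose from 0.284 to 3.08 CPM (3.85 ± 0.60, adjusted p = 0.000283). CALML5 (3.65), AFAP1L2 (3.43), the glycogen-targeting subunit PPP1R3C (3.25), SYNPO2 (3.25) and TMEM229B (3.22) rose too, and CLEC3A and the unnamed ENSG00000246792 each had 2 counts under the control compound. PLIN2, the coat protein of lipid droplets, fell from 127 ± 12.2 to 15.8 ± 1.61 CPM (-3.01 ± 0.16, adjusted p = 4.55e-08), and NIBAN1 from 22.3 ± 5.29 to 1.98 ± 0.591 CPM (-3.49 ± 0.26, adjusted p = 5.17e-07). The iron-binding LCN2 fell from 59.4 to 12.3 CPM (-2.27 ± 0.21, adjusted p = 4.51e-06) and the interferon-induced ISG15 from 403 ± 198 to 75.4 CPM (-2.42 ± 0.51, adjusted p = 0.00259). GEM (-2.72), VGF (-2.60), the lipase LIPG (-2.55), KLF2 (-2.38), the uridine phosphorylase UPP1 (-2.33) and PGM1 (-2.31) completed the decreases. These directions are relative to the control compound, not to untreated cells. Untreated cells had 0.528 CPM of LCN2 and 2.82 CPM of GEM, less than with either compound. They had 44.4 ± 32.4 CPM of CALML5 and 10.1 ± 3.99 CPM of ENSG00000246792, more than with either compound.

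Of 16 lists called in MCF7, 13 were down and 3 up, and 7 held with an estimated correlation, all of them down. Hypoxia response genes had 19 of 28 down, 2 up and 7 not passing (20 down when adjusted over the list alone; adjusted p = 1.23e-11 and 0.00199), including NDRG1 (from 235 to 85.1 CPM), LDHA (from 513 to 240 CPM) and P4HA1 (from 142 to 72.2 CPM). Immediate early and MAPK feedback genes had 13 down, 1 up and 6 not passing (14 down when adjusted over the list alone; adjusted p = 3.85e-10 and 0.00322), with DUSP1 (-1.20), FOSL1 (-1.64) and JUNB (-1.09). Endoplasmic reticulum chaperones had 11 down and 9 not passing (16 down when adjusted over the list alone; adjusted p = 9.09e-09 and 0.00322), with HSPA5 from 3530 to 1490 CPM. Cholesterol synthesis had 10 down, 1 up and 13 not passing (11 down when adjusted over the list alone; adjusted p = 7.03e-06 and 0.00322), with MSMO1 from 165 to 76.9 CPM. Targets of p53 had 9 down and 15 not passing (12 down when adjusted over the list alone; adjusted p = 2.75e-05 and 0.00322), with CDKN1A from 1530 to 730 CPM. NF-kB genes had 7 down, 1 up and 3 not passing (8 down when adjusted over the list alone; adjusted p = 0.00022 and 0.00997), with RELB (-1.39) and NFKB2 (-1.05). Iron metabolism had 10 down, 4 up and 12 not passing (5 up when adjusted over the list alone; adjusted p = 0.00598 and 0.0219): HMOX1 fell from 147 to 34.9 CPM and the ferritin FTH1 from 5350 to 1520 CPM.

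The other nine called lists of MCF7 lost their call with an estimated correlation. Upward were estrogen-responsive genes, with 11 up, 4 down and 13 not passing (12 up when adjusted over the list alone; adjusted p = 0.0149 and 0.0853), luminal markers, with 8 up and 12 not passing (adjusted p = 0.0267 and 0.07), and cell cycle genes, with 14 up, 1 down and 22 not passing (adjusted p = 0.0288 and 0.456). ESR1, the estrogen receptor itself, rose from 35 to 96.6 CPM, its target CA12 from 37.8 to 130 CPM, and the luminal factor GATA3 from 907 to 1350 CPM. ESR1 stood at 201 CPM in untreated cells, above both compounds. Downward were the ATF4 response, with 17 down, 2 up and 11 not passing (adjusted p = 1.25e-06 and 0.138), heat shock genes, with 10 down and 4 not passing (adjusted p = 3.38e-05 and 0.138), and glycolysis, with 10 down, 1 up and 9 not passing (12 down when adjusted over the list alone; adjusted p = 0.000558 and 0.144). NRF2 genes had 8 down, 2 up and 15 not passing (adjusted p = 0.00252 and 0.0853). Fatty acid oxidation had 5 down, 3 up and 14 not passing (6 down and 4 up when adjusted over the list alone; adjusted p = 0.0267 and 0.372), and fatty acid synthesis 5 down, 1 up and 9 not passing (8 down when adjusted over the list alone; adjusted p = 0.0472 and 0.496). Fatty acid oxidation did not pass without control compound 2 (0.0686), nor fatty acid synthesis without octyl-2HG 3 (0.114), control compound 3 (0.0679) or 4 (0.123) or with the block (0.0564), nor cell cycle genes without octyl-2HG 1 (0.125) or 2 (0.0722) or control compound 4 (0.101).

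**Figure D3:**
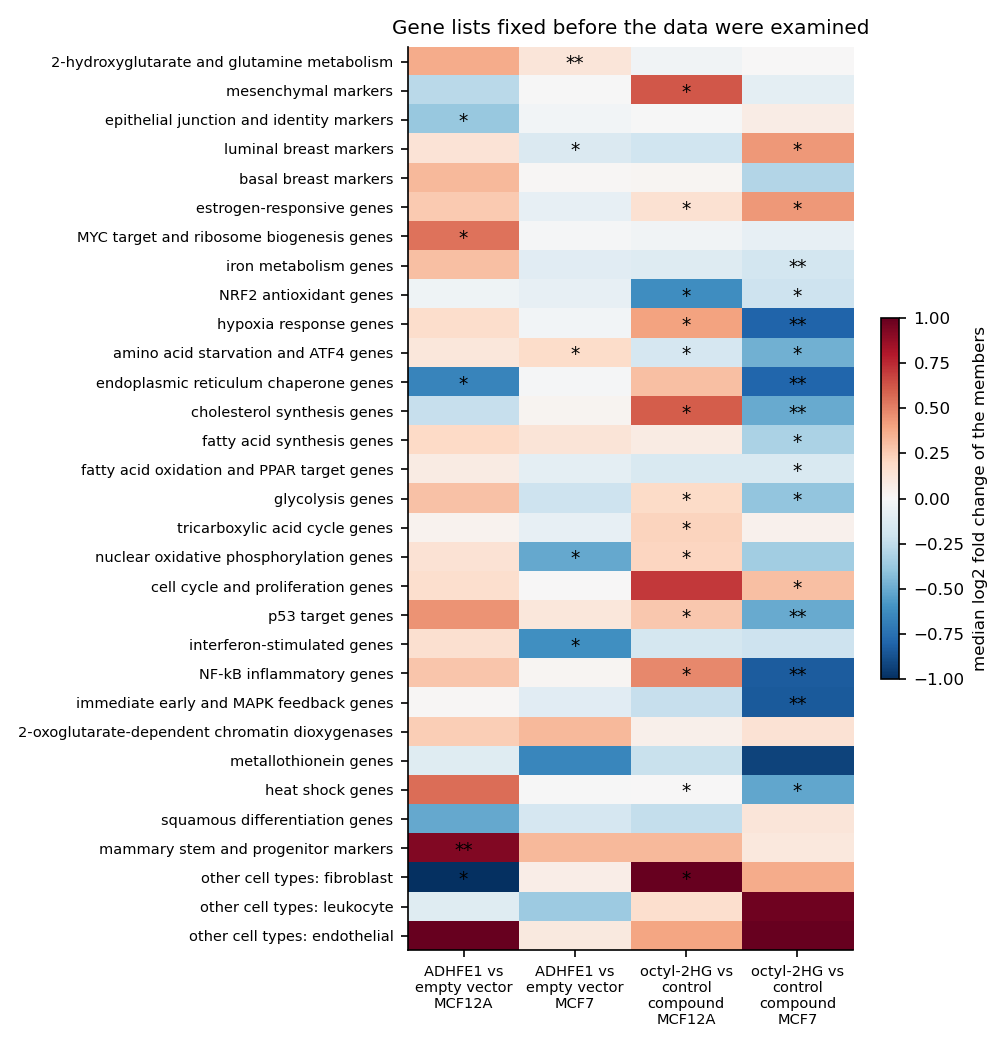
Colors give the median log2 fold change of each of 31 gene lists in 4 comparisons; 1 star marks an adjusted p under 0.05 and a pair of stars also with an estimated correlation, and colors are full at 1 and beyond. Hypoxia response genes had a median of 0.40 for octyl-2HG against the control compound in MCF12A and of -0.80 in MCF7.

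Comparison with untreated cells shows what each compound did from the starting level, since the control compound itself changed many genes. In MCF7, octyl-2HG called 7786 genes (3851 up, 3935 down, or 4757 up and 4451 down with the replicate number as a block) and the control compound 8788 (4168 up, 4620 down). CYP1A1, the aryl hydrocarbon receptor target, rose from 0.203 ± 0.137 CPM to 24.3 ± 5.96 with octyl-2HG (6.72 ± 0.36, adjusted p = 2.01e-09) and to 64 ± 3.8 with the control compound (8.12 ± 0.37, adjusted p = 1.87e-10). The stress cytokine GDF15 rose from 22.7 ± 6.85 CPM to 635 ± 156 and 1320 ± 320 CPM (4.81 ± 0.28 and 5.87 ± 0.30), and LCN2 from 0.528 to 12.3 and 59.4 CPM. BDKRB2 (5.25) and TGFBI (4.49) also rose with octyl-2HG, and CLGN (5.25) and GEM (5.09) with the control compound. Both compounds lowered ASCL1 (-5.09 and -6.47) and left 1 count of UGT2B15, a gene with close paralogs, against 10.7 CPM in untreated cells. AGR3 (-4.63), the deiodinase DIO2 (-4.58) and the unnamed ENSG00000202364 fell with octyl-2HG, and CALML5 (-6.47), LINC01522 (-7.41) and ENSG00000246792 (2 counts left) with the control compound.

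Untreated levels also place the genes that parted the compounds in MCF7. PLIN2 rose by 3.30 ± 0.17 with the control compound over untreated cells (adjusted p = 5.64e-10) and by 0.29 ± 0.15 with octyl-2HG, which did not pass (adjusted p = 0.129). Of the 4095 genes called between the compounds, 1872 were called against untreated cells in the same direction for both, and in 1695 of these the control compound was farther from untreated. Another 1400 were called only for the control compound, 469 only for octyl-2HG, 111 in opposite directions and 243 for neither.

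In MCF12A the comparisons with untreated cells called 8036 genes for octyl-2HG (4239 up, 3797 down, or 3962 up and 4137 down without untreated 2) and 6717 for the control compound (3752 up, 2965 down). ANGPTL4, a lipase inhibitor induced by PPAR factors and hypoxia, rose from 16.4 ± 1.11 CPM to 274 ± 23.5 with octyl-2HG (4.08 ± 0.13, adjusted p = 4.45e-15) and to 614 ± 130 with the control compound (5.25 ± 0.14, adjusted p = 8.22e-17). The activin subunit INHBA rose by 4.98 and 5.20, and BMP6 by 4.01 and 5.24. NGFR (5.24) and SERPINE1 (3.60, from 144 to 1760 CPM) were also among the largest increases with octyl-2HG, and NMRAL2P (4.43) and IL1RL1 (no count in untreated cells, at least 6.31-fold higher) with the control compound. IL1RL1 had only 26 counts over the control compound libraries. With the control compound MMP7 went from 3.25 CPM to no count, at least 66.5-fold lower, and TNNI2 (-6.09), SULT1E1 (-5.91), TNFSF10 (-5.50) and SELENOP (2 counts left) fell. The largest decreases with octyl-2HG were 5 gene IDs without a symbol (ENSG00000225840, ENSG00000239776, ENSG00000241530, ENSG00000241781 and ENSG00000243185). In untreated cells their SD was at least as large as their mean, and none of the 5 passed without MCF12A untreated 2. Of the 6475 genes called between the compounds in this line, 1571 were called against untreated cells in the same direction for both, and in 673 of these the control compound was farther from untreated. Another 1413 were called only for the control compound, 2381 only for octyl-2HG, 261 in opposite directions and 849 for neither.

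Because both compounds were set against the same untreated libraries, some correlation of their fold changes follows from that alone. The compounds shared 4443 genes called in the same direction in MCF12A (1779 if the lists were independent, 261 opposite) and 6072 in MCF7 (2202 if independent, 111 opposite). In 10 simulations with no compound effect but a shared control, no gene was shared in either line. Without an effect hardly any gene can be called in either comparison, so that result followed from the setting. It cannot tell how many of the shared calls came from the shared control. Simulated libraries were drawn independently, without the correlation of same-numbered libraries or the trends of the libraries that stood apart. Across genes, which are not independent replicates, Pearson's r of the log2 fold changes was 0.762 in MCF12A (0.56 in the simulations) and 0.827 in MCF7 (0.457). With no compound effect the simulated r is scaled by noise alone, so it does not give the part due to the shared control. The covariance of the log2 fold changes was 0.701 in MCF12A (0.0349 in the simulations) and 1.11 in MCF7 (0.039). When the 4 untreated MCF7 libraries were halved so that no control was shared, between 4507 and 5109 genes were shared, and r ran from 0.487 to 0.803. With 3 untreated MCF12A libraries no such halving could be made.

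The effect of octyl-2HG over the control compound differed between the lines in 4685 of 17242 genes (2633 higher in MCF7, 2052 higher in MCF12A). Hypoxia genes were among those that differed. The genes that follow were chosen after their values were seen, and the lists as wholes were not tested between lines. The difference, MCF7 minus MCF12A, was -2.45 ± 0.30 for NDRG1 (adjusted p = 7.77e-07), -1.97 ± 0.13 for P4HA1 (adjusted p = 2.79e-11), -1.64 ± 0.14 for LDHA (adjusted p = 2.27e-09) and -1.37 ± 0.17 for SLC2A1 (adjusted p = 6.3e-07). For CA9 it was -1.90 ± 1.48 and did not pass (adjusted p = 0.37). Sterol genes differed the same way, by -2.0 ± 0.25 for HMGCR and -2.42 ± 0.17 for MSMO1, as did the p53 targets MDM2 (-1.30 ± 0.14) and CDKN1A (-1.67 ± 0.19), the chaperone HSPA5 (-1.87 ± 0.21) and the mesenchymal genes SERPINE1 (-3.34 ± 0.19) and ITGA5 (-2.58 ± 0.16). Against untreated cells NDRG1 rose with both compounds in both lines, by 2.71 (octyl-2HG) and 1.70 (control compound) in MCF12A and by 2.13 and 3.60 in MCF7. P4HA1, LDHA and SLC2A1 did not all do so. In MCF12A they lay above every untreated library with octyl-2HG, but no control compound library exceeded the highest untreated one. In MCF7 LDHA lay between 235 and 249 CPM with octyl-2HG and between 445 and 514 CPM in untreated cells.

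**Figure D4:**
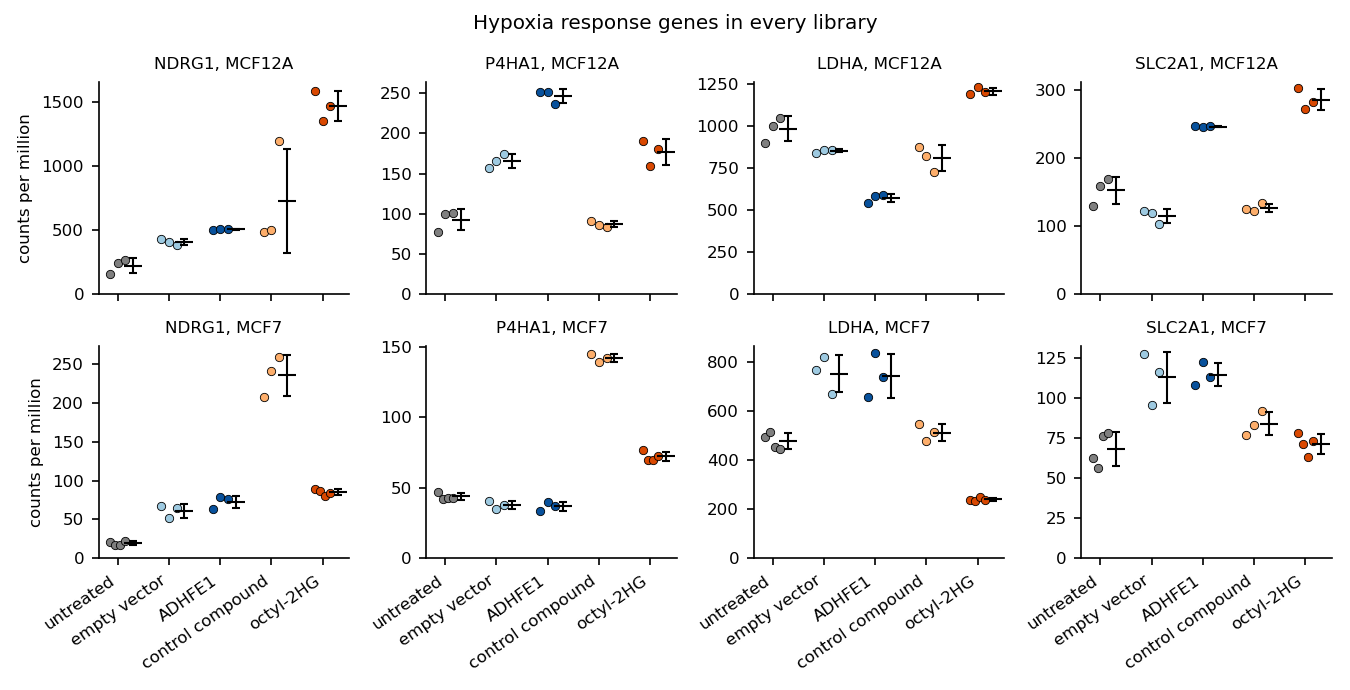
CPM of the hypoxia genes NDRG1, P4HA1, LDHA and SLC2A1 (chosen after their values were seen) in each library of the 5 groups of both lines; points are libraries and bars the mean ± SD. NDRG1 lay between 1350 and 1590 CPM with octyl-2HG and between 483 and 1200 CPM with the control compound in MCF12A, and between 80.5 and 89.2 CPM and between 207 and 258 CPM in MCF7.

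The genes that differed most between lines for octyl-2HG, by the rule, were BCAS1 (6.45), ENSG00000236673 (5.73), CAPN13 (5.20), the morphogen SHH (4.79) and SUGCT (4.78), higher in MCF7, and the basal keratin KRT5 (-6.99), EDN2 (-6.89), MMP7 (-6.61), CERS1 (-5.52) and DCN (-5.50), lower in MCF7. For ADHFE1 against vector the effect differed between lines in 5183 genes (2615 higher in MCF7, 2568 higher in MCF12A). Largest were HS6ST2 (12), the zinc finger genes ZNF607 (11), ZNF525 (10.7) and ZNF83 (9.12) and SLC44A5 (9.82), and in the other direction AUTS2 (-10.4), CCND2 (-8.08), RASAL1 (-7.40), PTPRZ1 (-7.22) and BARX2 (-7.01). Of these 20 genes, HS6ST2, ZNF607, ZNF525, AUTS2, RASAL1, BARX2, BCAS1, ENSG00000236673, SUGCT, MMP7 and CERS1 had no count in a group, and most of the rest few, so the size and order of the fitted differences depend on the prior count.

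Overlap of calls asks whether the enzyme and its product, given as an ester, moved the same genes. In MCF12A 1070 genes rose in both (973 if independent, 1-sided Fisher's exact p = 1.51e-05) and 1102 fell in both (1080 if independent, p = 0.226), while 2075 went in opposite directions (2050 if independent). Genes are not independent replicates, so these p-values are no measure of replication. The ADHFE1 calls of this line also carry the distance of the vector libraries from untreated cells. In MCF7 1 gene rose in both (0.855 if independent) and 8 fell in both (4.96 if independent), and 21 went in opposite directions (6.57 if independent). The 9 genes shared in MCF7 became 5, 2 and 2 without ADHFE1 1, 2 and 4, 33 with DESeq2, and 58 without the libraries that stood apart. Of these 21, 19 fell with ADHFE1 and rose with octyl-2HG, among them MME, RGS22, GPER1 and BCL2. ADHFE1 calls shared between lines were 2 up, ADHFE1 itself being 1 of them, and 8 down (1.56 and 7.48 if independent), and 11 were opposite (8.78 if independent, 13684 genes). The 10 in the same direction became 6, 4 and 4 without ADHFE1 1, 2 and 4 of MCF7, 5 without its empty vector 1 or 2, and 74 without the libraries that stood apart. Octyl-2HG calls shared between lines were 306 up and 335 down (384 and 399 if independent), and 1146 were opposite (784 if independent). The 641 in the same direction became 1151 without the libraries that stood apart, 1014 with length and GC trends removed and 387 without an expression filter. Across genes Pearson's r between ADHFE1 and octyl-2HG was 0.0848 in MCF12A and 0.123 in MCF7, and between the lines it was 0.0661 for ADHFE1 and -0.0796 for octyl-2HG.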

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

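Of the tests in this part, those of the empty vector libraries, those of the small number of ADHFE1 genes in MCF7, those of depth and of reads from other libraries for MCF7 octyl-2HG 3, and the splits for ADHFE1 against vector and for octyl-2HG against the control compound in MCF12A were chosen after the result was seen.

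The effect of ADHFE1 over vector differed between the lines, by an interaction test, in 5183 genes. The largest fitted differences, MCF7 minus MCF12A in log2, were HS6ST2 12, ZNF607 11, ZNF525 10.7, SLC44A5 9.82, ZNF83 9.12, AUTS2 -10.4, CCND2 -8.08, RASAL1 -7.40, PTPRZ1 -7.22 and BARX2 -7.01. In MCF12A, HS6ST2, ZNF607 and ZNF525 had no count with ADHFE1 and AUTS2, RASAL1 and BARX2 none with empty vector, so the size and order of their fitted differences depend on the prior count. Among 100 splits of the libraries within lines, 6 called as many genes (highest other 6471). The 11 other splits that left the MCF12A groups whole, and so kept that line's effect, called at least 4543 genes, and the 88 that mixed them at most 9, so the number of splits decides nothing about chance here. Several of these genes set the MCF12A empty vector group apart: HS6ST2, ZNF83 and SLC44A5 were high in it, and AUTS2 and CCND2 were low.

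The effect of octyl-2HG over the control compound differed between the lines in 4685 genes. The largest fitted differences were BCAS1 6.45, ENSG00000236673 5.73, CAPN13 5.20, SHH 4.79, SUGCT 4.78, KRT5 -6.99, EDN2 -6.89, MMP7 -6.61, CERS1 -5.52 and DCN -5.50. BCAS1, ENSG00000236673, SUGCT, MMP7 and CERS1 had no count in a group, so theirs depend on the prior count too. Of 100 splits only the real one called as many (highest other 1829). The 10 other splits that left the MCF12A groups whole called 699 to 1774 genes. The 2 that left only the MCF7 groups whole called 1307 and 1829, and the 87 that mixed both lines at most 121. Splits remove the effects within lines together with their difference. They thus argue against a chance arrangement of libraries within lines, and cannot decide about the difference between lines alone.

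The first pattern weighed is the distance of the MCF12A empty vector libraries from untreated cells. Of 29 genes at or under 0.1 CPM in untreated cells and at or over 5 CPM with empty vector, 23 were higher there than in every MCF7 library, which argues against MCF7 cells or RNA mixed in. The lowest ADHFE1 level among libraries labelled ADHFE1 was 22.4 times the highest among those labelled empty vector, against an exchange of these labels. Only 1 of the 29 genes was on in every ADHFE1 library, against carrying a vector or its selection as the reason for these genes. As they were picked at the extreme of the empty vector group, they cannot exclude a smaller effect shared by both vector groups. What also stays open is a wrong label from outside the series, another culture or clone of epithelial cells, or an effect of the empty vector alone. The series text names MCF10A where the labels read MCF12A. No other line's profile was used here, so none of these was tested.

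The second pattern is the small number of ADHFE1 genes in MCF7, 47 against 9691 in MCF12A. Depth is argued against, since the shallowest of the 6 MCF7 libraries had 14.9 M counts and the shallowest of the 6 in MCF12A 9.15 M. Removing each library's trend in length and GC content raised the count to 109, so that trend may hide some genes, but this is 1.07% of the MCF12A count with the same trend removed, which argues against it as the whole reason. The larger spread between MCF7 libraries (coefficient of variation 21.6% against 12.2%) is argued against as the whole reason, since the same fit called at least 4095 genes in every other MCF7 comparison, among them 4468 for empty vector and 5736 for ADHFE1 against untreated cells. What stays open is how much it hides (42.4% against 78.1% of simulated 2-fold changes were recovered, 81.5% of 4-fold changes in both lines, and 277 genes were called without the libraries that stood apart, of which empty vector 2 is in this comparison), a weaker response of MCF7, and the distance of the MCF12A vector group. Leaving out empty vector 2 alone gave 33 genes, so the rise to 277 did not come with that library by itself.

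In the groups of 4 libraries, 4 of 54 values tested had a library far from the others, where chance marks about 1 value in 20. MCF7 octyl-2HG 3 had 30769 genes with a count, and its group mates 22293 to 22991. It also had 0.0547 CPM of UGT2B15, which is 1 count, where the others had none. MCF7 untreated 1 had 3.57% of its counts on IDs without a symbol (1.12% to 1.22% in the others), and MCF7 untreated 2 had 0 CPM of CYP1A1 (0.251 to 0.302 in the others).

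The third pattern is the number of genes seen in MCF7 octyl-2HG 3. Thinned to the depth of the shallowest of the 4 libraries it still had 29989 genes (at most 22971 in the others), which argues against depth. Of 6929 genes seen in it and in none of its group mates, 35.1% had no count in any of the 31 other libraries, which argues against reads carried over from them. Genes otherwise silent were detected about evenly over the 22 autosomes, with the lowest share 0.731 times the median of 40.4%, which is consistent with reads from genomic DNA or unspliced RNA. No biological explanation was tested, as the design gives none for 1 library of a group.

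For ADHFE1 against vector in MCF12A (9691) and MCF7 (47), and in MCF12A for octyl-2HG against the control compound (6475), octyl-2HG against untreated (8036) and the control compound against untreated (6717), the 10 splits are too few for a share under 0.05; only the real 1 called any gene, and the highest other was 0. In MCF7 1 of 35 splits, the real one, called as many genes for octyl-2HG against the control compound (4095, highest other 1568), a share under 0.05. Same-numbered libraries correlated at 0.1 to 0.17 there. If numbers pair them, only 8 splits part as many pairs as the real one, too few for such a share. Whether the splits exclude chance thus depends on pairing, which the labels do not state. The split with 1568 genes placed octyl-2HG 1 with the control compound libraries. Octyl-2HG against untreated (7786, highest other 0) and the control compound against untreated (8788, highest other 5717) also had 1 of 35. In both, all same-numbered libraries were correlated above 0.1, so their numbers may pair the libraries. Only 8 splits of each part as many pairs as the real one, too few for a share under 0.05, and the highest other among them was 0 and 3949. The splits that parted fewer pairs called at most 0 and 5717 genes, the latter with untreated 4 beside the control compound libraries.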

How the results depend on the processing

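The tests added after the data were seen are those of the 2HG list without ADHFE1, with length and GC trends removed, without IDs that have no symbol, and without the 5 libraries that stood apart; DESeq2 was run on genes and not on lists. No list or named gene that passed did so in the other direction under any setting. Where up and down counts were close, the larger of them could be the other one: for octyl-2HG against the control compound in MCF7 (2216 up, 1879 down) with RLE scaling (2019, 2106), DESeq2 (2200, 2429) and without the libraries that stood apart (3399, 3540); for octyl-2HG against untreated in MCF12A (4239, 3797) without untreated 2 (3962, 4137); for the same in MCF7 (3851, 3935) without a filter (3407, 3342), with the block (4757, 4451), with trends removed (4491, 4382) and without octyl-2HG 2 (3431, 3426) or 4 (3401, 3377); and for the difference of the ADHFE1 effect between lines (2615, 2568) with the stricter filter (2357, 2437), DESeq2 (2734, 2763), trends removed (3107, 3183), and without ADHFE1 2 (2253, 2325) or 4 (2283, 2319) of MCF12A or ADHFE1 1 (2253, 2275) or empty vector 1 (2318, 2379) of MCF7. Where a value changed, the cause was not tested.

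Counts of called genes stayed within 1.5 times under a stricter filter, RLE scaling, no filter and without unnamed IDs in all 10 comparisons. The exception elsewhere was chiefly ADHFE1 against vector in MCF7, 47 genes: 174 with DESeq2, 112 with the replicate block, 109 with length and GC trends removed, 277 without the libraries that stood apart, and 2 when only its groups were fitted. Leaving out 1 library gave 18 to 33 (25, 18 and 19 without ADHFE1 1, 2 and 4, 24 without empty vector 1 and 33 without empty vector 2). Octyl-2HG against the control compound in MCF7 rose from 4095 to 6939 without the libraries that stood apart.

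Genes shared by ADHFE1 and octyl-2HG in MCF7 (9) became 33 with DESeq2, 28 with the block, 21 with trends removed and 58 without the libraries that stood apart; leaving out 1 gave 2 to 10 (5, 2 and 2 without ADHFE1 1, 2 and 4). ADHFE1 genes shared between lines (10) became 34 with DESeq2, 22 with trends removed and 74 without the libraries that stood apart; leaving out 1 gave 4 to 11 (6, 4 and 4 without ADHFE1 1, 2 and 4 of MCF7, and 5 without its empty vector 1 or 2). Octyl-2HG genes shared between lines (641) became 1014 with trends removed, 1151 without the libraries that stood apart and 387 without a filter.

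With the replicate number as a block the other counts kept within 1.5 times: in MCF12A 8717 for ADHFE1, 6010 for octyl-2HG against the control compound, and 7489 and 6177 for octyl-2HG and the control compound against untreated; in MCF7 5731, 9208 and 9774 for the comparisons of compounds in that order; 5571 and 5755 for the differences between lines. Same-numbered libraries were all correlated above 0.1 only for the MCF7 compounds against untreated cells. In no comparison did each library correlate best with its own number.

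Of 124 list results, 30 lost their call with an estimated correlation, and none gained one. In MCF12A for ADHFE1 these were epithelial junction (adjusted p = 0.651), MYC (0.558), endoplasmic reticulum (0.693) and fibroblast (0.649). For octyl-2HG in MCF12A they were mesenchymal (0.0533), estrogen (0.238), NRF2 (0.139), hypoxia (0.0911), ATF4 (0.666), cholesterol (0.171), glycolysis (0.647), tricarboxylic acid cycle (0.592), oxidative phosphorylation (0.666), p53 (0.469), NF-kB (0.171), heat shock (0.465) and fibroblast (0.171). For ADHFE1 in MCF7 they were luminal (0.125), ATF4 (0.873), oxidative phosphorylation (0.946) and interferon (0.128), and for octyl-2HG luminal (0.07), estrogen (0.0853), NRF2 (0.0853), ATF4 (0.138), fatty acid synthesis (0.496), fatty acid oxidation (0.372), glycolysis (0.144), cell cycle (0.456) and heat shock (0.138).

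Fry, which asks whether a list moved on balance and not whether it moved more than other genes, called 32 more and lost 2. For ADHFE1 in MCF12A it added 2HG (1.49e-05), mesenchymal (1.34e-05), luminal (8.18e-07), basal (0.000155), estrogen (0.00412), iron (0.0273), NRF2 (0.0305), fatty acid oxidation (0.0342), glycolysis (0.00147), p53 (0.00101), NF-kB (9.87e-06), dioxygenases (0.0123), metallothioneins (0.00441), heat shock (4.01e-06), squamous (0.0259) and leukocyte (0.00936). For octyl-2HG in MCF12A it added MYC (0.0257), iron (0.0341), endoplasmic reticulum (0.0144), fatty acid oxidation (0.00484), interferon (0.0168), immediate early (0.0257), dioxygenases (0.0253), stem (0.000206), leukocyte (0.0131) and endothelial (0.00256). In MCF7 it added estrogen for ADHFE1 (0.0349) and lost ATF4 (0.173) and oxidative phosphorylation (0.53); for octyl-2HG it added basal (0.0298), interferon (0.0207), metallothioneins (0.0402), stem (0.022) and endothelial (0.022).

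Other settings changed few lists. Without ADHFE1 the 2HG list lost its call for ADHFE1 in MCF7 (0.749, and 0.946 with an estimated correlation), the only comparison in which camera called it. Heat shock in MCF12A with octyl-2HG missed the threshold with the block (0.0614) and with trends removed (0.0577), as did fatty acid synthesis in MCF7 with octyl-2HG with the block (0.0564). For ADHFE1 in MCF7, glycolysis passed with the block (0.0332) and without the libraries that stood apart (0.0466), dioxygenases with the block (0.0123) and with RLE scaling (0.0462), and estrogen genes with trends removed (0.022) and without the libraries that stood apart (2.81e-05). Without those libraries endoplasmic reticulum genes passed in MCF12A with octyl-2HG (0.0229), and interferon genes in MCF7 with octyl-2HG (0.0437).

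Leaving out 1 library changed 28 of 775 list values. For ADHFE1 in MCF12A, NF-kB ran from 0.0245 to 0.138, passing without ADHFE1 2 or 3 (0.0245 and 0.033). For octyl-2HG in MCF12A, estrogen (0.00936 to 0.0582) and ATF4 (0.000115 to 0.0582) failed without control compound 4. Endoplasmic reticulum genes (0.0176 to 0.146) passed without octyl-2HG 3 or 4 or control compound 4 (0.0307, 0.0285 and 0.0176), fatty acid oxidation (0.039 to 0.0945) without control compound 3, and cell cycle (0.000672 to 0.22) without control compound 2 or 3 (0.000672 and 0.0272). For ADHFE1 in MCF7, luminal (0.00331 to 0.0509) failed without empty vector 1, ATF4 (3.83e-06 to 0.0533) without empty vector 4 and oxidative phosphorylation (4.55e-06 to 0.0703) without empty vector 2. Estrogen (8.76e-05 to 0.379) passed without ADHFE1 2 (0.0301) or empty vector 2, glycolysis (0.0239 to 0.289) without ADHFE1 2 or empty vector 4 (0.0409), and dioxygenases (0.0174 to 0.6) without ADHFE1 2 (0.0301), empty vector 1 (0.0294) or empty vector 4. For octyl-2HG in MCF7, fatty acid synthesis (0.00974 to 0.123) failed without octyl-2HG 3 (0.114), control compound 3 (0.0679) or 4, fatty acid oxidation (0.0102 to 0.0686) without control compound 2, and cell cycle (0.00255 to 0.125) without octyl-2HG 1 or 2 (0.0722) or control compound 4 (0.101), while oxidative phosphorylation (0.0423 to 0.789) passed without control compound 3.

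Of named genes, 71 of 1030 fold changes with 1 library left out lost their call, 48 of them in MCF7, mainly for ADHFE1. Depth limits the genes with a group at or near 0 counts, whose fitted values depend on the prior count.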

Other observations

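None of the tests in this part was fixed before the data were examined, and no explanation is offered for the values.

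The 5 libraries that stood apart did so in different ways. MCF7 empty vector 2, untreated 1, untreated 2 and control compound 2 had log2 CPM that changed by -0.204, -0.207, -0.26 and -0.145 per doubling of transcript length, against at least -0.00788 in the other MCF7 libraries. In MCF7 the main axis of differences within groups held 63.8% of their variance and its gene loadings had a Spearman correlation of 0.544 with transcript length, across genes, which are not independent replicates. In MCF12A that axis held 49.4%, with a correlation of 0.132. MCF12A untreated 2, the shallowest library, had 50.6% of its counts on IDs without a symbol.

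Empty vector against untreated cells called 4468 genes in MCF7 (2428 up, 2040 down), and ADHFE1 against untreated cells 5736 (2966 up, 2770 down). Of the 47 genes called between ADHFE1 and empty vector in MCF7, 42 were also called in the same direction between ADHFE1 and untreated cells, where in MCF12A 2604 of 9691 were.

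Lineage genes chosen after their values were seen differed in both directions between empty vector and untreated cells in MCF12A. In the order untreated, ADHFE1, octyl-2HG, control compound and empty vector, KRT17 stood at 50.7, 81.8, 22.6, 32.5 and 1440 CPM and KRT5 at 6560, 12000, 3160, 2490 and 3980 CPM. TP63 stood at 149, 291, 62.2, 74.7 and 51.5 CPM, and VIM at 995, 903, 2230, 1820 and 190 CPM. With empty vector KRT5 thus lay within the range of the other groups, and TP63 was near its levels with the compounds. KRT81 had 22.4 CPM in untreated cells and 702 CPM with empty vector. Both compounds lowered ESR1 in MCF7, from 201 CPM in untreated cells to 96.6 CPM with octyl-2HG and 35 CPM with the control compound, while it stood at 281 CPM with ADHFE1 and 244 CPM with empty vector.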
